A study of Bos taurus with 9 samples.

How the data were processed

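RNA sequencing was done on intercaruncular endometrium, the uterine lining between the caruncles, from cattle with a short uterine tract (group Short, 5 samples) and with a normal tract (group Normal, 4 samples). The labels give no batch, cycle stage or pairing. Each sample has a numbered title of its own, with a gap in the numbering, and the labels do not say whether a number marks an animal. Nothing in them says how the samples were taken from animals, so the errors below measure only a spread between libraries. The authors' fit also held 5 libraries outside the comparison (below), so the deposited errors do not rest on these samples alone.

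The authors deposited 1 table for the series, a DESeq2 result table of Short against Normal with 1 row for each of 21696 Ensembl genes. No value per sample is analysed here except as described below. Per the submitters' processing notes, HISAT2, SAMtools, HTSeq and DESeq2 were used with the genome build ARS-UCD1.2. Versions, annotation release, strand setting and filters are not given in the sources used here. Per the file headers, the table gives for each gene the mean normalized signal over libraries (counts divided by size factors by the authors), the log2 fold change, its standard error on the log2 scale, the Wald score, the p-value and the adjusted p-value. A deposited text column marks 521 genes as significant, and all 521 had an adjusted p-value under 0.05. Each deposited score equalled the log2 fold change divided by its standard error within 4.1e-14, and each deposited p-value equalled the two-sided normal p of that score within 2.9e-15. The adjusted p-values equalled a Benjamini-Hochberg adjustment over the 16615 genes that have one, within 7.1e-15. Of the other genes, 4619 had a p-value but a mean of at most 2.205, below the smallest mean with an adjusted p-value, 2.206. The remaining 462 had no p-value. In DESeq2, which the authors used, a gene with an outlying count in a library is left without a p-value by default; the table does not state the reason. A positive fold change was read as higher in Short, from the order of the groups in the table's name and from the number of libraries on each side (below).

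The design fixed before the data were examined was a count test where counts per sample were at hand, and otherwise a description of the authors' deposited values, which was the case that applied. All fold changes, standard errors and adjusted p-values are thus those of DESeq2 as the authors deposited them. The table names genes by Ensembl identifier only. The reference table used here (37063 genes) held 0 Ensembl identifiers, so no gene was given a name or a position. For the same reason the 36 gene lists fixed before the data were examined (hormone receptors, prostaglandin synthesis, HOX and WNT genes, cell types, inflammation and others) could not be tested. The naming rule called for genes with a symbol, the largest fold changes among genes with an adjusted p-value under 0.05 and a mean above the median of tested genes (156.5). It was applied without the symbol, and the first 2 identifiers in each direction are printed.

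The number and the relative depth of the libraries behind the deposited means were recovered from the lowest means. A mean under 2 times the smallest one holds a single read, and the 825 such genes fell on 14 distinct values, so the means are over 14 libraries. The sign of the authors' fold change for a gene with a single read gives the side of the contrast that library is on. On the positive side were 5 libraries and on the negative side 4, while 5 gave a fold change of exactly 0 and were on neither side. The libraries on neither side still entered the deposited means and the fit that gave the standard errors and p-values. The 5 and 4 libraries match the number of Short and Normal samples. No library was tied to a sample, and letters name the libraries in order of size factor. Every gene with a mean under 2 was then searched for the set of whole reads in 14 libraries whose sum gives its mean within 1e-14. Of 4485 genes, 4484 had exactly 1 such set and 1 had several. All 551 resolved genes with no reads in the 9 compared libraries had a deposited fold change of exactly 0, and none of the 3933 others had. The 825 single-read genes, which gave the sides, are counted here, so their agreement is not a separate check. For the 2086 genes with reads on both sides, the log2 ratio of the recovered group means and the deposited log2 fold change had a Pearson correlation of 0.993 across genes and a median absolute gap of 0.04. Whether the authors applied any shrinkage of fold changes is not given in the sources used here. In a test on simulated data, 1000 of 1000 simulated genes were recovered exactly, and 0 of 986 means that were no sum of whole reads were matched. These reads belong to genes without an adjusted p-value in the deposited table, and they were compared between sides with exact permutation tests over all splits of the 9 libraries into 5 and 4.

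The alternatives for the deposited values fixed before the data were examined were a fold limit of 2, an adjusted p-value threshold of 0.1, an adjustment over all genes with a p-value, a minimum mean of 10, and a re-centring of the score on an empirical null (its median, 0.109, and its scaled median absolute deviation, 1.19). In simulated scores with a shifted and widened null, 160 unchanged genes were called before and 10 after the re-centring. That null was normal, a form that the re-centring undoes, and was made wider than the deposited scores. The direction of the drop was thus fixed in advance. The drop does not show how many of the deposited calls are false. The changed genes were given scores far from the null, all in the same direction. That 200 of 200 of them were called both times was therefore fixed in advance. It does not show how many true changes the re-centring loses. Alternatives that need a value per sample were not run. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.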

Results

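Gene expression was measured by RNA sequencing in intercaruncular endometrium of cattle, the part of the uterine lining that lies between the caruncles and carries the uterine glands. There were 5 samples labelled Short and 4 labelled Normal, and the question put by the study was which genes differ in expression with a short uterine tract, a condition its title ties to infertility. The authors' deposited table lists 21696 genes by Ensembl identifier, with their mean normalised count and the fold change of Short over Normal. Gene names are not paired with the identifiers here, so the groups of genes described below are groups by direction, size of change and expression level. The mean normalised counts of all genes summed to 7483809, and the 10 highest genes held 5.19% of that sum. Total counts per sample are not analysed here. The size factors recovered from the lowest means, which measure relative depth, were 1.06 ± 0.069 (SD, n = 5) in the Short libraries and 1.01 ± 0.076 (SD, n = 4) in the Normal libraries. They did not differ beyond the spread between libraries (two-sided exact permutation test, p = 0.341). The deposited means are means over 14 libraries, of which 9 are those compared. A mean is therefore the level of a gene in the whole set, not in either group. The standard errors and p-values come from the same fit, so the calls below do not rest on the 9 compared libraries alone.

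In the authors' deposited table, 521 of 16615 tested genes (3.14%) differed between Short and Normal endometrium at an adjusted p-value under 0.05 (DESeq2 Wald test, Benjamini-Hochberg adjustment). Of these, 373 were lower and 148 were higher in Short, so that 71.6% of the changed genes fell. A change of at least 2-fold was found for 279 of the genes that fell and 112 of those that rose. A change of at least 16-fold was found for 22 and 24 genes, respectively. The median size of the change was 1.46 on the log2 scale for genes that fell (interquartile range 0.99 to 2.33) and 1.57 for genes that rose (1.01 to 3.05). The largest excess of falls was among abundant genes: the genes that fell had a median mean of 275 normalised counts, and those that rose 112. After the statistic was re-centred on an empirical null, 194 genes were called, 174 lower and 20 higher, and the share of falls was 89.7%.

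The gene with the largest fall under the naming rule was ENSBTAG00000052892, which also had the smallest adjusted p-value of all genes. The authors' deposited table gives it a mean of 202 normalised counts and a log2 fold change of -8.85 ± 0.71 (SE, adjusted p-value = 1.04e-31 by DESeq2). Its level in Short was 461-fold lower, with a 95% Wald interval from 177-fold to 1206-fold. The deposited mean allows an average of at most 708 normalised counts per Normal library and, at that fold, about 1.53 per Short library, so the size of this fold rests on a group near 0. The next largest fall under that rule was that of ENSBTAG00000021118, with a mean of 249 normalised counts. Its deposited log2 fold change in the authors' deposited table was -4.90 ± 1.10 (SE, DESeq2 adjusted p-value = 0.00103), a level 29.9-fold lower with an interval from 6.76-fold to 133-fold. The largest rise under that rule was that of ENSBTAG00000015685, with a mean of 287 normalised counts and, in the authors' deposited table, a log2 fold change of 4.75 ± 1.40 (SE, DESeq2 adjusted p-value = 0.0287). That is a level 27.0-fold higher in Short, with an interval from 4.01-fold to 182-fold, and its adjusted p-value was 0.206 after the statistic was re-centred. The second was ENSBTAG00000055240, a gene of high abundance with a mean of 4926 normalised counts. It was 22.4-fold higher in Short (interval 6.02-fold to 83.4-fold), with a log2 fold change of 4.49 ± 0.97 (SE) and a DESeq2 adjusted p-value of 0.000554 in the authors' deposited table. No value per library could be given for these 4 genes, so how many samples show each change is not known.

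The balance of rises and falls changed with the expression level. Among genes with a mean of 1000 normalised counts or more, 65 fell and 5 rose in Short, that is 92.9% falls among the 70 changed genes of the class. Among genes with a mean from 200 to 1000, 160 fell and 52 rose. The classes from 50 to 200, from 10 to 50 and from 2.21 to 10 held 83, 48 and 17 genes that fell against 47, 33 and 11 that rose. Over all genes of a class with a fold change other than 0, called or not, the median log2 fold change went the other way at low expression. It was 0.24 for means from 2.21 to 10, 0.19 from 10 to 50 and 0.08 from 50 to 200, then -0.01 from 200 to 1000 and -0.04 above. In the lowest of these classes 59.4% of those genes had a fold change above 0, and in the highest 46.1%. Genes are not independent replicates, so no p-value was computed for this trend. Centring the fold changes on a running median over expression gave 416 falls and 129 rises. Of these 545 calls, 478 were among the 521 deposited ones and 67 were not.

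**Figure D1:**
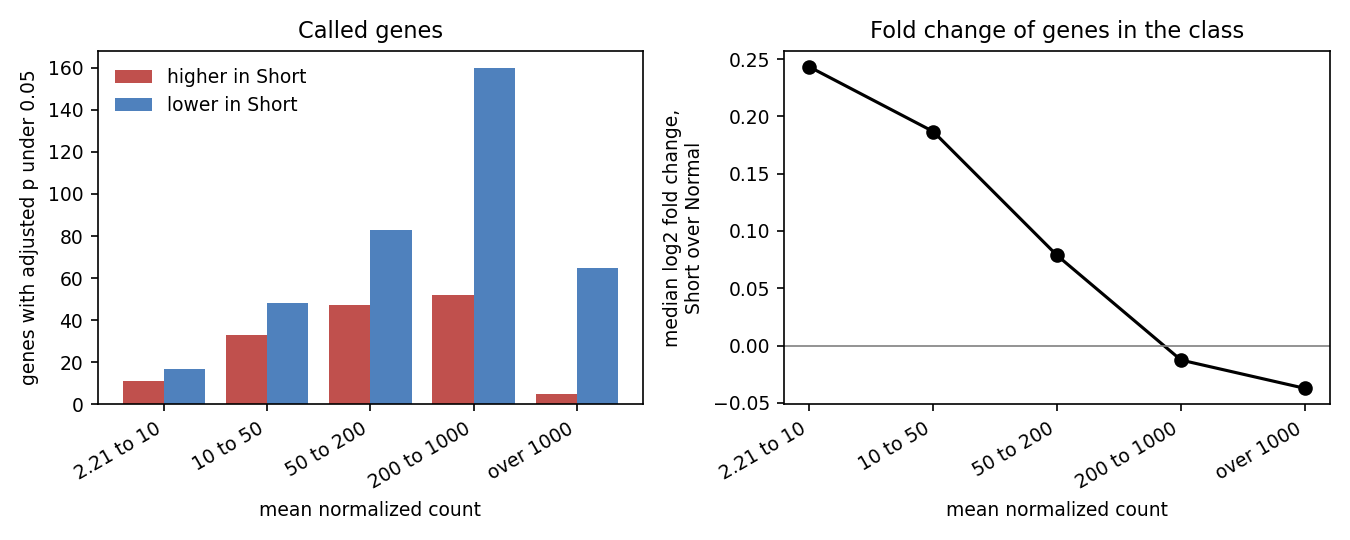
Left, the number of genes with an adjusted p-value under 0.05 in the authors' deposited table by class of mean normalised count, as bars for genes higher and lower in Short. Right, the median log2 fold change of Short over Normal of all genes in each class with a fold change other than 0. It goes from 0.24 in the lowest class to -0.04 in the highest, while falls outnumber rises among called genes in every class.

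The size of change that could be called depended on abundance. A call required a score of at least 3.16. At the median standard error of its class, a gene had to change by 8.40-fold with a mean from 2.21 to 10, by 3.84-fold from 10 to 50, by 2.33-fold from 50 to 200 and by 1.99-fold from 200 to 1000. Above 1000 it had to change by 2.23-fold. Genes with a smaller standard error than their class were called at smaller changes, down to 0.43 on the log2 scale for falls and 0.52 for rises. The 16094 tested genes without a call are not shown to be unchanged. At an unadjusted p-value under 0.05 the authors' deposited table holds 2191 tested genes, where 831 would lie if no gene changed and the scores had the unit spread that their p-values assume; their scaled median absolute deviation was 1.19.

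A group of 462 genes (2.13% of those listed) had no p-value in the authors' deposited table and could not enter the counts of called genes. Those with a fold change other than 0 are still part of the medians and shares over the genes of a class. The median mean of the 462 genes was 94.6 normalised counts and the highest was 12675. Of these genes, 258 had a fold change above 0, 169 below 0 and 35 exactly 0. They included 129 genes with a fold change of at least 2-fold, and 10 with an absolute log2 fold change above 8, against 2 such genes among the 521 called. Had the normal p-value of the deposited score been used for them, 539 genes would have been called, 380 lower and 159 higher.

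Genes with a mean under 2 normalised counts were listed by the authors but not given an adjusted p-value. The whole reads recovered for 4484 of these low genes allowed comparisons between libraries, which were chosen after the data were seen. Divided by the size factor, the reads in low genes came to 2697 ± 186 (SD, n = 5) in the Short libraries and 2307 ± 91.1 (SD, n = 4) in the Normal libraries, a ratio of 1.17. The Short libraries lay between 2512 and 2899 and the Normal libraries between 2184 and 2405, so that the groups did not overlap (two-sided exact permutation test, p = 0.0159, adjusted over 3 tests of the libraries 0.0238). The 5 libraries outside the comparison lay between 2436 and 2813. Libraries of the same group were more alike in these genes than libraries of different groups. The mean Pearson correlation of log2(reads over size factor + 1), taken across genes, was 0.230 over the 16 pairs of the same group and 0.173 over the 20 pairs of different groups. The difference of 0.057 was larger than in any of the other splits of the 9 libraries, of which the highest gave 0.043 (one-sided exact permutation test, p = 0.00794, the smallest that these splits can give, adjusted 0.0238).

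**Figure D2:**
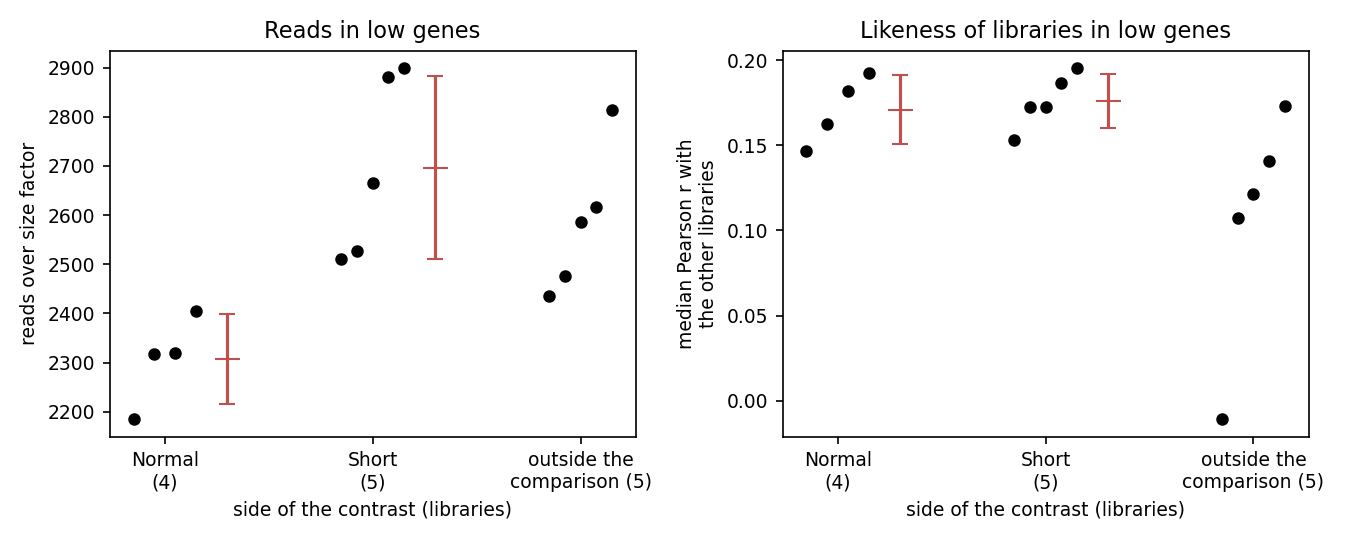
Each point is 1 of 14 libraries recovered from the deposited means, on the Normal or Short side of the contrast or outside it; horizontal bars and whiskers are the mean and SD of the 4 Normal and 5 Short libraries. Left, reads in 4484 low genes divided by the size factor, on an axis that does not start at 0, with all Short libraries above the highest Normal library at 2405; right, the median Pearson correlation of each library with the other libraries across those genes, with 1 library outside the comparison at -0.011 and the others at 0.107 or more.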

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

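All tests in this part were chosen after the results were seen. Dixon's gap test, which has little power in groups of 5 and 4, marked no Short or Normal library in size factor, reads in low genes, low genes detected, their share with 1 read or likeness to the other libraries.

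The authors' fit behind the deposited table held 5 libraries that are on neither side of the contrast, and these held reads of their own. In the low genes this did not set them apart: each was the only library with reads for 49 to 116 genes. For a Short library that number was 87 to 124, and for a Normal library 65 to 86. In the table, 599 genes had a fold change of exactly 0, which in the resolved low genes always went with no read in any of the 9 compared libraries. Of these, 48 had a mean of at least 2 normalised counts, and the highest mean was 88.0. Reads were not recovered for genes with such means, so that they too lack reads in the compared libraries is an extrapolation from the low genes.

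One of these 5 libraries was unlike all others. Its detected low genes held 5.91 reads each on average, against 1.85 to 2.35 in the other 13 libraries, and 14.1% of them held a single read, against 45.8% to 55.4%. It held 2010 reads in low genes, against 2194 to 3196 in the other libraries, but detected 340 low genes, against 1033 to 1484. These values argue against a small number of reads in low genes as the cause. Its size factor was 0.777, and the poorest other library, scaled to that in proportion, would give 906 detected genes. A size factor need not measure depth in a library so unlike the others, and its total counts are not known. Its depth over all genes therefore remains open. Whether it was built from few distinct molecules that were each read many times remains open: its commonest number of reads above 1 was 5 and that of every other library was 2, but this restates the observation. Whether it came from another tissue or cell type also remains open, as no gene names are paired with the identifiers here. Its highest correlation with any other library, taken across the low genes only, was 0.029. In the other 13 libraries the highest correlation was 0.178 to 0.295. No biological explanation was tested.

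Whether the missing p-values come in part from these libraries remains open. Of the 48 genes with a fold change of exactly 0 and a mean of at least 2, 68.8% had no p-value, against 2.48% of the 17163 other genes with such a mean. A gene with no reads in the compared libraries can have an outlying count only outside them, but the table does not state why a p-value is missing. For the 427 genes without a p-value and with a fold change other than 0 the table does not show which library was outlying.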

How the results depend on the processing

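The alternatives that gave missing p-values from the score, left out genes with a fold change of exactly 0, or centred the fold changes, and all those on recovered reads, were chosen after seeing the data. Re-centring the score on an empirical null moved the number of called genes from 521 to 194, of rises from 148 to 20 and of falls from 373 to 174, and ended the call of ENSBTAG00000015685 (adjusted p-value 0.206); the cause was not tested. The deposited score had a scaled median absolute deviation of 1.19, where 1 is assumed by its p-value. Under the other 8 alternatives the number of calls stayed within 1.5 times, between 391 with a fold limit of 2 and 706 at a threshold of 0.1, the share of falls between 69.0% and 77.2%, and the 4 named genes kept their calls and directions. Adjusting over all genes with a p-value gave 457 calls, and a minimum mean of 10 gave 503, of which 493 were among the 521. Centring on the median of tested genes, 0.04, gave 543 calls with 77.2% falls, and on a running median over expression 545 with 76.3%. In the low genes, the ratio of Short to Normal reads went from 1.15 to 1.19 as each of the 9 libraries was left out. The difference in mean correlation went from 0.046 to 0.065, and the exact permutation p-values of both were at most 0.0357. As the groups did not overlap in these reads, the ratio was bound to stay above 1. Its p-values mostly reflect the number of splits and are not separate evidence. With genes of a mean under 1, genes with at most 5 reads, or genes unseen in the odd library, the ratio was 1.19, 1.14 and 1.16, and the difference in correlation was 0.032, 0.041 and 0.057. No paired analysis was possible because the labels give no number shared between groups and the table holds no value per sample. Other count tests, normalisations, surrogate variables, leaving out replicates in the authors' fit, other splits of the samples in that fit and all gene list settings were not run, as they need counts per sample or gene names. Depth is known only as size factors, which differed by 1.2-fold at most among the compared libraries.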

Other observations

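All tests in this part were chosen after the results were seen. Of the p-values of tested genes, those above 0.5 would place the share of unchanged genes at about 85.2% if p-values of unchanged genes are spread evenly, which the width of the scores leaves open.

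Relative to the size factors, genes of low expression were higher in Short than in Normal. This held for the median fold change of tested genes with a low mean and for the reads recovered for genes below the authors' filter. Such relative values do not tell a rise of low genes from a fall of abundant ones. In the recovered reads, the 5 libraries outside the comparison, at 2436 to 2813, also lay above the highest Normal library at 2405. Whether the Short libraries were high or the Normal libraries low is therefore not known. The trend argues against a scaling error common to all genes, since the median log2 fold change of tested genes with a mean under 10 exceeded that of genes with a mean from 200 to 1000 by 0.25 (95% bootstrap interval 0.19 to 0.30, across genes). An equal number of background reads added to every gene would leave those with a mean from 10 to 50 at a median log2 fold change of 0.01. Their observed median was 0.18 (0.15 to 0.22). Both intervals resample genes, which share the same libraries. They do not measure the spread between libraries, so both arguments hold for these libraries only. For the recovered reads, all 5 Short libraries lay above the highest Normal library, so the difference was not that of a single library. The lowest ratio with 1 library left out, 1.15, adds nothing to this. Without overlap the ratio was bound to stay above 1. For the fold changes of the tested genes no library could be left out, since they come from the authors' fit. A background that scales with gene length, a batch that follows the groups and a difference in cell types or cycle stage between Short and Normal tracts remain open and untested.

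The likeness of libraries within a group in low genes was checked against all other splits. Only 1 split of the 9 libraries into 5 and 4, the real one, gave a difference in mean correlation as large as 0.057, and the highest of the others gave 0.043, so chance can be excluded only as far as that count of splits goes. It is the permutation test already given for these libraries and not separate evidence. These genes had no adjusted p-value in the authors' table, so none of them is among the called genes. A batch that follows the groups would give the same picture, and the labels give none.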
